A study of Homo sapiens with 13 samples.

How the data were processed

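ChIP-seq peak lists of H1 human embryonic stem cells were compared between WT cells and a ZNF263 knockout clone, for H3K4me3, H3K27ac and H3K27me3, together with a list from FLAG ChIP in KO cells that expressed FLAG-tagged ZNF263. Per the labels, chromatin from formaldehyde-fixed cells was sonicated and libraries were prepared from ChIP and input DNA without size selection. Groups were taken from the sample titles. The titles give replicate numbers for the endogenous ZNF263 ChIP alone. The labels of these 2 libraries and of their input point to the FLAG list, so no separate endogenous peaks were analysed here.

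Bowtie2, Picard and the hg19 build are named in the submitters' processing notes, with no version. The peak names in the deposited files begin with MACS. The version of the caller, the input used for each list and any pooling of libraries are not given in the sources used here. Each deposited list gives chromosome, start, end, peak name and a score for each peak, with no header. The score is the authors' value from peak calling, and its scale is not given in the sources used here. The lowest score was 40 in the H3K27ac and H3K27me3 lists and 50 in the H3K4me3 and FLAG lists. The labels name a p-value threshold for the former lists only, and the lowest scores differ, so numbers of peaks are not comparable between marks. Scores of 3100 or more made up 42.9% of WT H3K4me3 peaks and 41.9% of KO H3K4me3 peaks, 16.4% of WT H3K27me3 and 16.1% of KO H3K27me3 peaks. Scores near that ceiling do not rank peaks. Scores were used only within a list, to describe, rank, filter, group and match peaks. The FLAG list lacks 186 of its 23152 peak numbers, so some peaks appear to have been removed after calling. Its name ends in noblk, which may stand for removal of blacklisted regions, and no histone list is named so. A histone peak in a removed region may lack a FLAG peak for that reason.

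Overlaps were computed with bedtools 2.31.1, and a peak was shared when it overlapped a peak of the other list by at least 1 bp. Peaks with no such overlap were called WT-only or KO-only. A peak absent from a list can be a region just under the caller's threshold, and a deeper or cleaner library yields more peaks, so numbers of exclusive peaks move with depth as well as with biology. Depth is unknown because the lists give no read counts, and no floor was given. Shares have Wilson 95% intervals, and differences of shares have Newcombe intervals. FLAG peaks were placed at random 100 times on their own chromosome, within 1 Mb bins that held a peak of any list. Exclusive peaks were set against 10000 random sets of the same size drawn from the same list with matched width deciles. With 1 library per arm no test between genotypes was made. Tables were handled in python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

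The overlap and matching steps were tested on simulated data made from the 17537 WT H3K27ac peaks. The overlap differed from a direct count for 0 of 500 peaks. In 200 simulations in which FLAG overlap depended on width alone, 4% of matched results fell outside the central 95% of random sets, against 100% without matching. Overlap was then planted at random in 5% of the tested peaks, some of which overlapped already, so the excess was below 5 points. It was found in 100% of simulations.

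The rule for named regions was fixed before the data were examined: the 5 WT-only and the 5 KO-only peaks of each mark with the largest score, and the 10 FLAG peaks with the largest score. Alternatives fixed at that time were an overlap of 50% of the smaller peak, peaks up to 1 kb apart counted as shared, the upper 50% of each list by score, lists of equal length, peaks up to 3 kb apart merged, and autosomes alone. Matching on score, strong exclusive peaks against the complete other list, and lists of equal length for the FLAG comparison were chosen after the data were seen. The gene table used here belongs to another build, so it served only to find which chromosome a gene family lies on. Promoters, gene lists, the position of the ZNF263 gene and DNA motifs at FLAG peaks were therefore not analysed here.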

Results

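The data came from H1 (WA01), an established human embryonic stem cell line, and from an H1 clone in which ZNF263, a C2H2 zinc finger transcription factor, had been deleted with Cas9 (KO). Chromatin immunoprecipitation with sequencing (ChIP-seq) mapped 3 histone marks in wild-type (WT) and KO cells. H3K4me3 is typical of promoters, H3K27ac of active promoters and enhancers, and H3K27me3 of regions held by Polycomb. A FLAG antibody mapped ZNF263 in KO cells that expressed a FLAG-tagged copy, and the peaks of the list its label names are called FLAG peaks. The name of that list includes KO, OE and Flag, where OE usually stands for overexpression. The level of the tagged protein is not given here, so FLAG peaks need not all be sites of endogenous ZNF263. The 13 samples formed 12 groups, with 6 histone libraries, 1 FLAG library, 2 libraries made with an antibody against endogenous ZNF263 in WT cells, and 4 inputs. The 7 peak lists of the histone and FLAG libraries were analysed, and separate peaks of the endogenous ChIP were not analysed here. Each arm of each comparison held 1 library, so no test between genotypes was made and the differences have no replicate check. The lists carry no read counts, and the depth of the libraries is unknown. All intervals are 95% intervals that cover the counting of peaks only, by Wilson's method for shares. Coordinates are hg19, counted from 1, and no gene was assigned to a peak because no hg19 annotation was used here.

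The first question was where FLAG peaks lay relative to marked chromatin. FLAG peaks lay mostly either at H3K4me3 peaks or away from all 3 marks. Of the 22966 FLAG peaks, 50.004% (49.4 to 50.7) overlapped a WT H3K4me3 peak, against a mean of 5.00% when the same peaks were placed at random. H3K27me3 peaks of WT cells held 28.1% (27.5 to 28.6) of FLAG peaks and H3K27ac peaks 20.7% (20.1 to 21.2), against 2.68% and 2.75% at random. In WT, 10844 FLAG peaks (47.2%) touched none of the 3 marks, where random placement gave 93.1%. These unmarked FLAG peaks were weak, with a median score of 68.6. FLAG peaks with H3K4me3 and H3K27me3 but not H3K27ac numbered 5033 and had a median score of 141. The 3685 with H3K4me3 and H3K27ac but not H3K27me3 had a median of 121, and the 917 with all 3 marks 168.

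**Figure D1:**
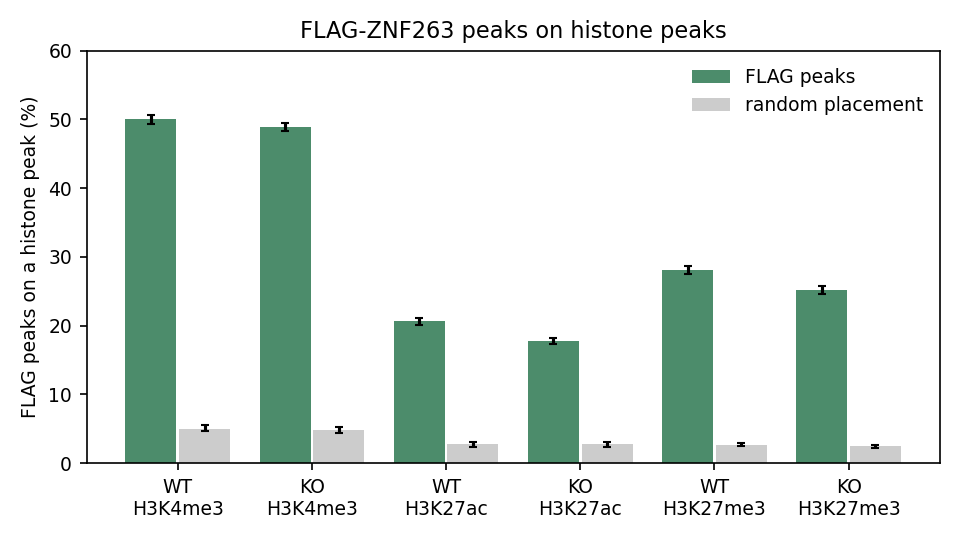
Bars give the percentage of the 22966 FLAG-ZNF263 peaks that overlap a peak of each histone list in WT and KO (green, Wilson 95% intervals) and the mean of 100 random placements (grey, lowest to highest). The largest share is 50.004% on WT H3K4me3 peaks, and every random mean is 5.00% or lower.

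The 10 FLAG peaks with the largest scores varied in the marks they carried. The largest, at chromosome 21, 16213271 to 16215015 (score 3100), and the next, at chromosome 1, 3184618 to 3188278 (score 3015), overlapped no histone peak in WT or KO. The third, 8744 bp wide at chromosome 19, 52190531 to 52199274, carried H3K4me3 in both genotypes and H3K27ac in KO only. Both H3K4me3 and H3K27me3 were present in both genotypes at chromosome 7, 100805166 to 100812269, and at chromosome 9, 133533478 to 133545004. The FLAG peak at chromosome 6, 143264419 to 143269335, carried all 3 marks in WT and lacked H3K27me3 in KO. The peak at chromosome 16, 1424611 to 1430717, carried H3K4me3 in both and H3K27ac in WT only. Of the 10, 6 overlapped a WT H3K4me3 peak and 7 a KO H3K4me3 peak.

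The next comparison asked which marked regions differed between WT and KO cells. Most H3K4me3 regions were shared: 3535 WT peaks (12.3%, 12.0 to 12.7) had no KO peak and 1980 KO peaks (7.30%, 6.996 to 7.61) had no WT peak. H3K27ac had nearly equal numbers of exclusive peaks, with 4310 WT-only peaks (24.6%, 23.9 to 25.2) and 4365 KO-only peaks (24.8%, 24.2 to 25.5). H3K27me3 had 2575 WT-only peaks (21.6%, 20.9 to 22.4) and 1143 KO-only peaks (11.0%, 10.4 to 11.6). Bases covered in both genotypes made up 82.1% of all covered bases for H3K4me3, 77.9% for H3K27me3 and 61.2% for H3K27ac.

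The lists themselves were similar in size for H3K27ac, with 17537 peaks over 40.6 Mb in WT and 17571 over 41.4 Mb in KO. H3K4me3 had 28660 peaks over 81.5 Mb in WT and 27126 over 78.2 Mb in KO. H3K27me3 had 11906 peaks over 52.2 Mb in WT and 10375 over 50.3 Mb in KO. The median width of the KO H3K27me3 list was larger, 3454 bp against 3081 bp. Shared H3K27me3 peaks differed less, with medians of 3835 bp in KO and 3758 bp in WT. Exclusive H3K27me3 peaks were narrow, with medians of 1646 bp for the 2575 in WT and 1565 bp for the 1143 in KO. Exclusive peaks were mostly weak. WT-only H3K4me3 peaks had a median score of 71.5 against 2941 for WT peaks shared with KO, and WT-only H3K27me3 peaks 61.4 against 563. For H3K27ac the medians were 56.7 for WT-only and 56.4 for KO-only peaks, against 170.5 and 161 for the shared peaks of each list. With both lists of a mark reduced to equal numbers by score, H3K27me3 had 1492 WT-only and 1479 KO-only peaks, and H3K4me3 had 2519 and 2459. Near-equal numbers follow from lists of equal length and say nothing of where the WT excess comes from.

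**Figure D2:**
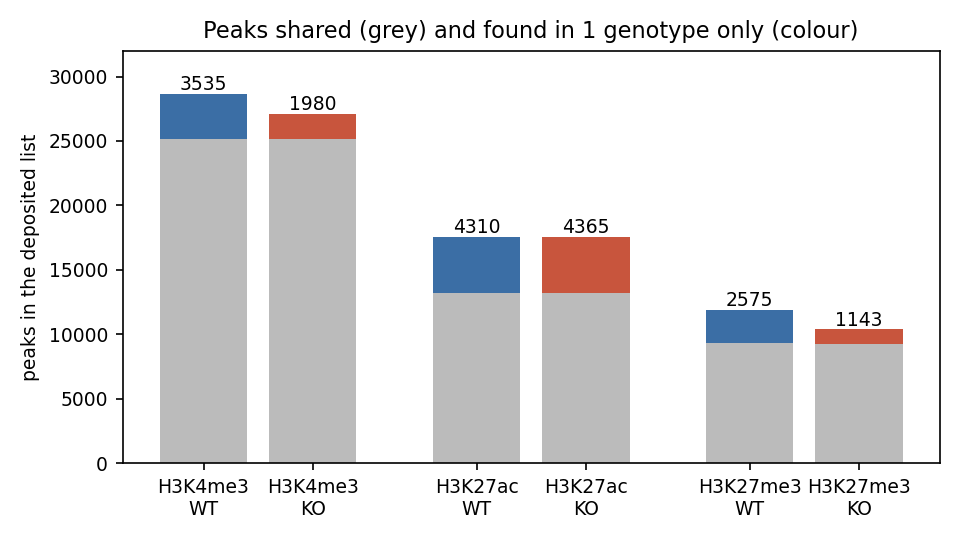
Bars give the number of peaks in each deposited list, split into peaks that overlap a peak of the other genotype (grey) and peaks that do not (blue for WT, red for KO), with the number of the latter above each bar. WT-only and KO-only H3K27ac peaks are nearly equal in number (4310 and 4365), and WT-only peaks outnumber KO-only peaks for H3K4me3 and H3K27me3.

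Among WT-only H3K4me3 peaks the 5 with the largest scores lay on chromosomes Y, 19, 1, 16 and 10. The highest, at chromosome Y, 2708913 to 2712078, had a score of 3100 and no KO H3K4me3 peak within 52.8 kb. The region at chromosome 19, 10462722 to 10465729, carried H3K4me3, H3K27ac and a FLAG peak, and neither mark had a peak there in KO. At chromosome 1, 155263852 to 155265970, H3K4me3 and H3K27me3 were both present in WT and both without a peak in KO. The WT-only H3K4me3 peak at chromosome 16, 65263953 to 65270311, was 6359 bp wide and carried H3K27ac in both genotypes. The peak at chromosome 10, 11783288 to 11785637, held a FLAG peak.

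KO-only H3K4me3 peaks were led by a 3850 bp peak at chromosome 19, 13317328 to 13321177, with a score of 3100. It carried H3K27ac in KO and not in WT, and held a FLAG peak. The KO-only H3K4me3 peaks at chromosome 2, 238810364 to 238811717, at chromosome 18, 76149926 to 76151798, and at chromosome 20, 62084164 to 62087238, also held FLAG peaks. At the chromosome 18 region H3K27me3 was KO-only as well, and at the chromosome 20 region H3K27ac was. The fifth, at chromosome 6, 58141076 to 58143413, carried no other mark and no FLAG peak.

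The 5 WT-only H3K27ac peaks with the largest scores all lay on H3K4me3 peaks that were present in both genotypes. The highest, at chromosome 10, 99257035 to 99259362 (score 535), also carried H3K27me3 in both genotypes and held a FLAG peak. The peak at chromosome 6, 44223638 to 44225999, held a FLAG peak too. Those at chromosome 3, 110687111 to 110690816, at chromosome 2, 101617738 to 101621933, and at chromosome 19, 41219925 to 41224141, did not. KO-only H3K27ac peaks were different in place, since the highest, at chromosome 6, 126501113 to 126504792 (score 523), had no H3K4me3 peak in either genotype and no WT H3K27ac peak within 71.5 kb. The KO-only H3K27ac peak at chromosome 12, 119655616 to 119658956, was also off H3K4me3. Those at chromosome 6, 57381755 to 57389461, at chromosome 5, 140514252 to 140516219, and at chromosome 8, 92081053 to 92083360, lay on shared H3K4me3, and the chromosome 5 peak held the only FLAG peak among these 5.

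WT-only H3K27me3 peaks with the largest scores all overlapped a WT H3K4me3 peak. At chromosome 16, 66610253 to 66615989 (score 3100), which held a FLAG peak, and at chromosome 3, 127631869 to 127635571, KO had neither mark. The region at chromosome 22, 51167757 to 51173096, likewise had neither mark in KO, although a KO H3K27me3 peak lay 0.646 kb away. The WT-only H3K27me3 peaks at chromosome 5, 140869066 to 140874080, and at chromosome 20, 641916 to 646826, overlapped H3K4me3 peaks in both genotypes, and the chromosome 20 peak held a FLAG peak. Within the chromosome 5 region, however, the WT H3K4me3 peak at 140870398 to 140872617 (score 1683) overlapped neither mark in KO. None of the 5 largest KO-only H3K27me3 peaks overlapped a WT H3K4me3 peak. A pair of them were neighbours on chromosome 13, at 114799049 to 114805826 and 114806042 to 114809365, and both held FLAG peaks. The peak at chromosome 18, 76150317 to 76152505, coincided with the KO-only H3K4me3 peak named above. The others, at chromosome 7, 4847507 to 4850428, and at chromosome 1, 49820334 to 49824308, carried no other mark.

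The central comparison was whether the regions that differed between WT and KO were those with FLAG peaks. Labels of the endogenous ZNF263 libraries from WT cells also point to the FLAG list, and whether their reads entered it is not given in the sources used here. In the complete lists WT-only peaks overlapped FLAG peaks more often than KO-only peaks did for all 3 marks. For H3K27ac, 23.2% (22.0 to 24.5) of WT-only and 7.10% (6.38 to 7.90) of KO-only peaks held a FLAG peak, a difference of 16.1 points (Newcombe interval 14.7 to 17.6). H3K27me3 gave 35.4% (33.6 to 37.2) and 12.3% (10.6 to 14.4), a difference of 23.04 points (20.3 to 25.6). For H3K4me3 the shares were 10.4% (9.45 to 11.5) and 4.19% (3.39 to 5.17), 6.22 points apart (4.85 to 7.54). These contrasts were smaller within strata of chromosome, number of nearby H3K4me3 peaks and width of the overlapping H3K4me3 peak. The odds ratio for holding a FLAG peak, WT-only against KO-only, was 3.96 pooled and 2.12 within strata for H3K27ac. For H3K27me3 it was 3.89 pooled and 1.72 (1.33 to 2.22) within strata, and for H3K4me3 2.66 and 1.85 (1.41 to 2.43). Shared peaks held FLAG peaks most often, at 43.3% of WT H3K4me3, 28.3% of WT H3K27ac and 52.4% of WT H3K27me3 peaks. Seen from the FLAG peaks, those with H3K27ac numbered 4745 in WT and 4079 in KO, those with H3K27me3 6445 and 5786, and those with H3K4me3 11484 and 11232.

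**Figure D3:**
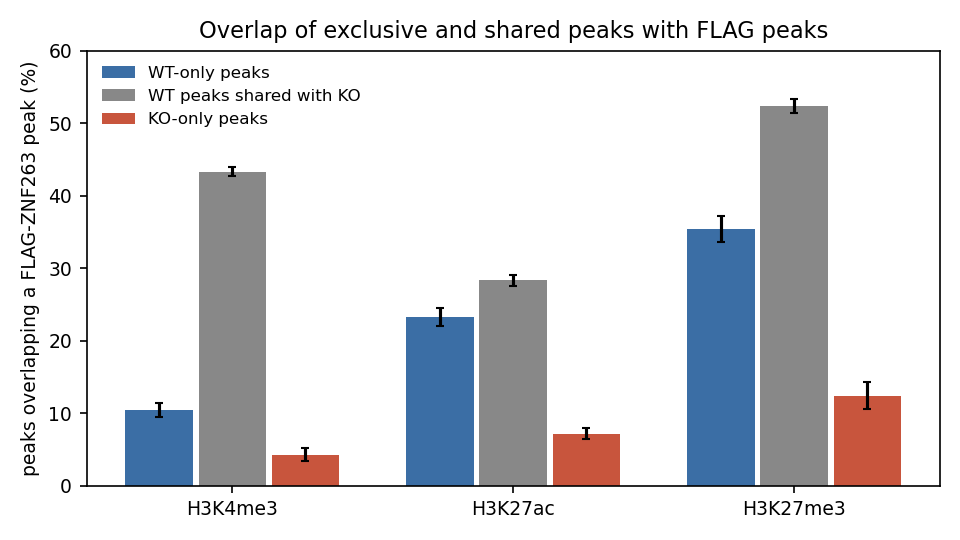
Bars give the percentage of peaks that overlap a FLAG-ZNF263 peak among WT-only peaks (blue), WT peaks shared with KO (grey) and KO-only peaks (red) of each mark, with Wilson 95% intervals. WT-only peaks lie above KO-only peaks for each mark, by 16.1 points for H3K27ac, and shared peaks are the highest of the 3 classes.

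H3K27ac differed in direction between peaks with and without a FLAG peak. H3K27ac peaks with a FLAG peak numbered 4751 in WT and 4044 in KO, a difference of -14.9%, and those without one 12786 and 13527, a difference of 5.80%. For H3K27me3 the corresponding differences were alike, -13.1% with and -12.6% without a FLAG peak. For H3K4me3 they were -2.44% with and -7.24% without one. The KO excess of H3K27ac peaks without a FLAG peak lay off H3K4me3. Exclusive H3K27ac peaks without one numbered 1921 in WT and 2710 in KO there, against 1387 and 1345 on H3K4me3. The opposite direction was thus not seen on H3K4me3. Against 10000 random sets of WT peaks of matched width, the WT-only share with a FLAG peak lay above all sets for H3K27ac (random mean 19.1%) and H3K27me3 (32.4%). In the upper 50% of each list by score, where a peak counts as WT-only even if a weaker KO peak overlaps it, H3K27ac stayed at percentile 99.97 and H3K27me3 dropped to 69.795, within the random range. KO-only shares lay below all sets for each mark in the complete lists. The H3K4me3 WT-only share of 10.4% lay below all width-matched sets (mean 14.6%). This direction turned in the upper 50% of each list, an alternative fixed before the data were examined, at percentile 99.975, but only 4 of the 911 peaks WT-only there had no peak in the complete KO list. It also turned when sets were matched on score as well, a setting chosen after seeing the data, with a random mean of 9.20%.

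The H3K27ac difference was also present among strong peaks, here those in the upper 50% of their list by score. This comparison was chosen after the data were seen. Only 12 WT-only and 13 KO-only H3K27ac peaks lay in the highest of 4 score classes of their lists. Among WT-only H3K27ac peaks from the upper 50% of their list by score, 176 of 378 (46.6%, 41.6 to 51.6) held a FLAG peak, against 30 of 338 KO-only peaks (8.88%, 6.29 to 12.4). The difference was not seen for the other marks, on few peaks. For H3K27me3, 23 of 54 WT-only peaks (42.6%, 30.3 to 55.8) and 3 of 7 KO-only peaks (42.9%, 15.8 to 75.0) held a FLAG peak, and for H3K4me3 1 of 4 and 1 of 1 did.

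The place of H3K27ac also differed between genotypes. H3K27ac peaks on H3K4me3 numbered 12983 in WT and 12244 in KO, and those off H3K4me3 4554 and 5327. On H3K4me3, 40.4% (38.4 to 42.4) of the 2327 WT-only H3K27ac peaks held a FLAG peak, against 17.5% (15.7 to 19.4) of 1630 KO-only peaks. The exclusive peaks on H3K4me3 without FLAG were nearly equal in number, 1387 in WT and 1345 in KO. Off H3K4me3 FLAG peaks were rare in both, at 3.13% of 1983 WT-only and 0.914% of 2735 KO-only peaks.

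Combinations of marks at H3K4me3 peaks addressed bivalent chromatin, in which H3K4me3 and H3K27me3 lie together. Bivalent peaks were fewer in KO, 8338 (30.7%, 30.2 to 31.3 of H3K4me3 peaks) against 9583 (33.4%, 32.9 to 34.0) in WT. Peaks with all 3 marks numbered 1343 (4.69%, 4.45 to 4.94) in WT and 770 (2.84%, 2.65 to 3.04) in KO. Of the 9583 WT bivalent peaks, 7908 (82.5%) overlapped both marks in KO, 1230 (12.8%) H3K4me3 only, 324 (3.38%) H3K27me3 only and 121 (1.26%) neither. Of the 8338 KO bivalent peaks, 7927 (95.1%) overlapped both marks in WT. FLAG peaks lay at 61.6% of WT bivalent peaks, against 20.9% of WT H3K4me3 peaks with neither other mark and 33.4% of those with H3K27ac only. Of the WT peaks with all 3 marks 72.7% held a FLAG peak. In KO 568 of these 1343 peaks (42.3%) still overlapped both H3K27ac and H3K27me3, while 567 of the 770 KO peaks with all 3 marks (73.6%) overlapped both in WT. In the lists reduced to equal numbers, WT had 8900 bivalent peaks and KO 8338.

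Chromosomes differed in the KO to WT ratio of H3K27ac peak number, from 0.838 on chromosome 19 to 1.12 on chromosome 4, with 11 of 22 autosomes below 1. The ratio was also low on chromosomes 17 (0.867) and 22 (0.864). For H3K4me3 and H3K27me3 the ratio was below 1 on all 22 autosomes, with medians of 0.947 and 0.871. Chromosome 19 had the lowest ratio for H3K27me3 as well, 0.798.

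**Figure D4:**
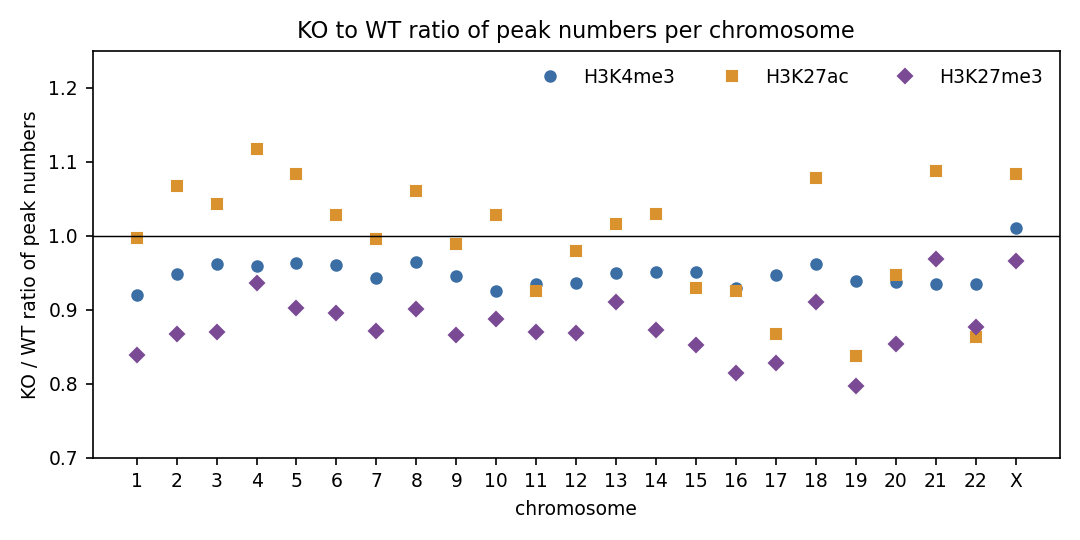
Points give the KO to WT ratio of the number of peaks on each of the 22 autosomes and X for H3K4me3 (blue circles), H3K27ac (orange squares) and H3K27me3 (purple diamonds), and the line marks a ratio of 1. H3K27ac ratios spread from 0.838 on chromosome 19 to 1.12 on chromosome 4, on a vertical axis that does not start at 0.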

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

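The strong exclusive peaks against the complete other list, the matching on score and the equal numbers for the FLAG comparison were chosen after the result was seen. Of 129 alternatives for 34 results, 96 gave a like value, 28 moved, 1 became weaker and 4 reversed. Ratios of peak number and covered length, and the H3K27ac percentiles, were among the like values under each alternative run. Keeping the upper 50% of each list by score shortens both lists by construction, so a peak WT-only there can overlap a weaker KO peak: WT-only and KO-only peaks became 911 and 144 for H3K4me3, 1805 and 1831 for H3K27ac, and 986 and 248 for H3K27me3. FLAG peaks then on WT and KO H3K4me3 numbered 6443 and 6087, on H3K27ac 2209 and 1921, and on H3K27me3 3403 and 3038. Bivalent peaks numbered 3947 in WT and 3025 in KO, and peaks with all 3 marks 199 and 120. The H3K4me3 difference in FLAG share became 18.1 points and the change of FLAG peaks with H3K4me3 -5.53%. The percentile of WT-only peaks turned to 99.975 for H3K4me3 and dropped to 69.795 for H3K27me3, and the cause was not tested. Matching on score as well as width turned the H3K4me3 percentile to 99.935 (99.98 in separate random draws). The random mean fell from 14.6% to 9.20%, so the low percentile depended on leaving score unmatched. WT-only H3K4me3 peaks had a median score of 71.5, against 2941 for shared WT peaks. Why they lay above the score-matched sets was not tested. Equal numbers of peaks lowered WT-only H3K27me3 peaks to 1492, near the KO-only number by construction, and the H3K27me3 difference in FLAG share became 26.3 points. An overlap of 50% gave 18.9 points for it, and the cause was not tested. Strong exclusive peaks against the complete other list numbered 4 and 1 for H3K4me3, 378 and 338 for H3K27ac, and 54 and 7 for H3K27me3. Their WT-only minus KO-only difference in FLAG share was 37.7 points for H3K27ac, -75 for H3K4me3 and -0.265 for H3K27me3, where the last 2 rest on few peaks. Promoter and gene list alternatives, motif alternatives, matching on promoters, and peak number in the upper 50% were not run, for want of an hg19 annotation and genome or because the number is fixed. No paired analysis was possible because each arm held 1 library. Depth is unknown and limits every count of exclusive peaks.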

Other observations

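The tests of regions without both marks, of deletion and of the widest H3K27me3 peaks were chosen only after the result was seen. H3K27me3 formed a few very wide domains that were alike in both genotypes. The widest in WT were 147 kb at chromosome 12, 54313970 to 54460857, 145 kb at chromosome 7, 27124944 to 27270287, 135 kb at chromosome 17, 46594193 to 46728741, and 132 kb at chromosome 2, 176928137 to 177060531. The KO peaks at these places were 145 kb, 144 kb, 135 kb and 133 kb wide. A candidate explanation is that they are the 4 HOX clusters, developmental genes held by Polycomb in stem cells, since HOXC, HOXA, HOXB and HOXD genes lie on chromosomes 12, 7, 17 and 2. Chance would place 4 peaks of the WT list on these chromosomes, 1 on each, with a probability of 0.000222, but the explanation was found from these chromosomes, so this match does not test it, and no hg19 annotation was used to place the genes.

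The X chromosome carried few FLAG peaks for its H3K4me3 peaks, 0.250 per WT H3K4me3 peak against an autosome median of 0.800 and a lowest autosome value of 0.582 on chromosome 6. Chromosome Y was lower still, 0.179, on 5 FLAG and 28 H3K4me3 peaks. The highest value was 1.36 on chromosome 22. H3K27me3 peaks per WT H3K4me3 peak were also lower on X, 0.312 against an autosome median of 0.416, while H3K27ac was near the median, 0.604 on both. The copy number of X and Y was not taken into account, and the cause of the low FLAG values was not tested.

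H3K27ac peaks found in 1 genotype were mostly WT-only where they held a FLAG peak, with an odds ratio of 3.96 (3.46 to 4.54) over 8675 exclusive peaks, and WT-only peaks had the higher FLAG share on 22 of 22 autosomes. Exclusive peaks that were themselves weak are argued against as the whole cause, since among strong exclusive peaks the odds ratio was 8.95 (5.84 to 13.7). That comparison was chosen after the data were seen, and the other genotype can still lie just under the caller's threshold. The strong peaks were not split by chromosome or H3K4me3. Over all 8675 exclusive peaks the odds ratio was 3.59 (3.13 to 4.11) within chromosomes and 2.95 (2.57 to 3.40) within classes of local H3K4me3 peak number. It was 2.52 (2.15 to 2.95) within classes of H3K4me3 peak width, and 2.12 (1.79 to 2.52) within all 3 together. The last value was still above 1 but short of the bound set in advance, so a part that comes from the 3 together cannot be told apart. Loss of ZNF263 binding is a hypothesis that may account for the rest, but it was not decided. The WT-only share in the highest of 4 classes of FLAG score, 80.2% (75.5 to 84.1), had an interval that overlapped that of the lowest, 74.4% (69.4 to 78.8). Without matching, WT H3K27ac peaks with a FLAG peak lacked a KO peak less often (21.1%) than those without one (25.9%). KO H3K27ac peaks with a FLAG peak lacked a WT peak in 7.67% of cases, against 30.0% without one. A difference between clones, base composition, depth and reads from WT cells in the FLAG list also stay open, with 1 clone and 1 library per arm. The FLAG list is named for KO cells and Flag, however, which speaks for KO reads without settling it.

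H3K4me3 and H3K27me3 were absent together in KO from 121 of 9583 WT bivalent regions, against 62.7 if the 445 absences of H3K4me3 and the 1351 of H3K27me3 were independent. The reverse comparison also held an excess, since 22 of 8338 KO bivalent regions had neither mark in WT, against 4.64 if independent. Draws matched on the score deciles of both marks gave 11 to 23 regions for the reverse, which takes in the 22. For the WT regions they gave 68 to 88, below the 121. These 121 regions were mostly weak, with a median H3K4me3 score of 90.1, and 19 scored 500 or more. Scores within a decile were not matched, so the draws cannot decide whether weak peaks account for the 121. A deletion from the clone cannot be told apart: 27 of the 121 regions (22.3%, 15.8 to 30.5) held a FLAG or KO H3K27ac peak. This argues against it for these 27 only, if the FLAG list holds KO reads alone. The list is named for KO cells and Flag, but the labels of the endogenous WT libraries point to it too. Without that list the share was 0.826% (0.146 to 4.53). That value lies below the share of KO bivalent peaks with H3K27ac (770 of 8338). It decides little, since KO bivalent peaks hold KO H3K4me3 and these regions do not. Depth and a change of chromatin state were not tested.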
